A study of Mus musculus with 6 samples.

How the data were processed

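RNA sequencing of mouse colon was analysed in 6 libraries, 3 from Adamts4 knockout animals (KO) and 3 from wild-type animals (WT), all after 7 days of 2.5% dextran sodium sulfate (DSS). Total RNA was extracted with Trizol and libraries were made with the SMARTER mRNA-Seq kit, per the labels' protocols. The submitters' processing notes name GRCm38, mm10 and mm39 without saying which step used which. The aligner, the counting program and the annotation release are not given in the sources used here, nor is whether reads were counted by strand. Overlapping or antisense genes and near-identical copies therefore carry an uncertainty that the counts cannot settle. The knockout allele, the strain, the sex and the litter of the animals are likewise not given in the sources used here.

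The deposited table holds 21899 genes with Ensembl identifiers, of which 30 have no symbol. Read counts per gene and library are whole numbers and were used as the authors deposited them. The TPM values of the authors are scaled to the same total in each library and served only for an alternative test. The deposited log2 fold change of each gene equals the log2 ratio of the KO to the WT mean TPM. The deposited p-value and its false discovery rate came from the authors' own comparison, and no tool is named for it. For all 17705 genes with a deposited p-value below 1, a DESeq2 Wald test computed here on the same counts gave the same p-value within 0.1%. Columns of group means were not used.

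The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with TMM factors and the default expression filter by group, which left 14553 genes. Calls had a Benjamini-Hochberg adjusted p below 0.05 with no fold minimum. The common dispersion was 0.084, a biological coefficient of variation of 29.0%, with 4.14 prior degrees of freedom. Fold changes are KO minus WT on the log2 scale, with a standard error derived from the F statistic, which is approximate. Levels are CPM scaled by the TMM factors, as mean ± SD over the 3 libraries of a group. Any adjusted p below is from edgeR over all genes tested unless another tool or "over the list alone" is named.

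Before the data were examined, 37 gene lists with 652 genes were fixed, covering cell types of the colon, pathways and signs of sample quality, together with the rule for the genes named and the main alternatives. Each list with at least 4 tested members (36 lists) was tested with camera of limma 3.58.1, at a preset inter-gene correlation of 0.01 and with an estimated correlation, and with fry. Fry's directional p asks whether the members move one way on balance and does not compare the list with other genes. Pathways were taken from the deposited KEGG annotation, keeping those with 10 to 500 tested genes. Genes within 10 Mb of Adamts4 were compared with all others by a two-sided Fisher's exact test, with positions from the GENCODE M21 annotation of GRCm38, matched by identifier for 14532 tested genes. The sex-linked list had no gene above the filter. Its Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had at most 4, 2, 2 and 0 counts in any library, which argues against male animals in either group. Of the listed genes, 3 had no matching row.

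The genes named were Adamts4; the 10 largest changes in each direction among called genes whose KO and WT values did not overlap and whose mean was at least 1 CPM in the higher group; in each list the 2 to 4 members with the smallest p; and Vcan, Acan and Bcan. Predicted genes, immunoglobulin segments and Y-linked genes were left out of the rule and summarised. Where fewer than 10 genes passed, the smallest unadjusted p-values filled the places.

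On counts simulated for the same libraries, edgeR recovered 28.4% of genes changed by 1 log2 unit, 89.6% of those changed by 2 and 95.5% of those changed by 3, over 14451 genes, with 10 false calls among 152. DESeq2 recovered 56.7%, 94.0% and 98.5% over 14553 genes, with 51 false calls among 217. The simulated counts followed dispersions estimated by edgeR and held no library that stood apart from its group. These shares therefore may not carry over to the real libraries. There edgeR left genes changed by more than 2 log2 units uncalled, such as Mmp8. Camera with the preset correlation called 0 of 100 random lists of unchanged genes in these simulated libraries, whose genes were drawn independently.

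The alternatives were other scaling factors (median-ratio and upper-quartile), DESeq2 1.42.0, limma-voom, no count filter, a filter of at least 1 CPM in at least 3 libraries, the replicate number as a block, leaving out each library in turn, a minimum of 1 log2 unit, an adjusted p below 0.1, and limma on log2(TPM + 1). Median log2 fold changes of all tested genes lay at 0.03 with TMM and median-ratio factors and at 0.01 with upper-quartile factors. Total counts per library ran from 15786214 to 22932125. Intervals of count ratios and floors cover counting error only, and the interval of a median over genes covers the spread between those genes, not between libraries. A floor of 3 counts per library was used wherever a group was at 0.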

Results

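Gene expression in the colon was compared between Adamts4 knockout mice and wild-type mice, 3 libraries each, after 7 days of 2.5% DSS. DSS is a sulfated polysaccharide that injures the colonic epithelium and produces an acute colitis. ADAMTS4 is a secreted metalloproteinase that cleaves large proteoglycans such as aggrecan, brevican and versican. The comparison asks how colon RNA levels under DSS differ between animals with and without this protease. Strain and litter are not given. A difference in genetic background between the groups therefore cannot be told apart from loss of the protease in any comparison below. Untreated animals were not analysed here, so each value sets one genotype against the other under the same treatment.

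The 3 KO libraries held 20348172, 15786214 and 19081623 counts and the 3 WT libraries 22932125, 19093788 and 17895970. Between 16333 and 16601 genes had a count in each, and the 10 most abundant genes took 10.1% to 13.5% of the counts. Mitochondrially encoded genes took 4.03%, 7.66% and 9.50% of the counts in KO 1, KO 2 and KO 3, and 6.05%, 4.29% and 4.46% in WT 1, WT 2 and WT 3. KO 3 stood apart on the first principal component, which held 42.9% of the variance, with a score of 73.1, while KO 1 (-16.6) lay among the WT libraries (-6.88 to -47.0). Fibroblast, endothelial and collagen genes were low in KO 3, where Col1a1, a collagen gene chosen after its values were seen, had 2048 counts against 6423 to 15322 in the other libraries. No pair of libraries agreed within sampling noise, the smallest chi-square per degree of freedom being 43.0. The labels give each library its own number within a genotype, but do not say that each came from 1 animal, so p-values measure the spread between these samples.

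Adamts4 (ENSMUSG00000006403, chromosome 1, 171250421 to 171260637 on GRCm38) had no count in any KO library and 48.3 ± 8.94 CPM in the WT libraries (SD, n = 3). Against the floor of 3 counts per library it was at least 289-fold lower in KO (edgeR adjusted p = 0.00213). The KO values lay below the WT values in all 6 libraries, which gave an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows. Its call held under each of the 13 alternative fits, with adjusted p between 2.76e-20 and 0.0171.

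The KO colons had lower levels of the chemokine genes Cxcl1, Cxcl2 and Cxcl13, the growth factor gene Ereg and the protease gene Mmp3, and a higher level of Igfbp2. Cxcl1 and Cxcl2, ligands of the neutrophil receptor CXCR2, fell from 26.8 ± 10.3 to 2.23 ± 1.02 CPM and from 14.8 ± 8.17 to 1.11 ± 0.423 CPM (log2 fold changes of -3.59 ± 0.42 and -3.73 ± 0.48, SE; adjusted p = 0.0434 and 0.0495). Cxcl13, the chemokine that draws B cells to follicles, fell by 3.04 ± 0.38 on the log2 scale (adjusted p = 0.0483). Ereg, an EGF receptor ligand made in the wounded gut, fell from 128 ± 17.8 to 20.3 ± 8.14 CPM (-2.65 ± 0.30, adjusted p = 0.0379). Igfbp2, an insulin-like growth factor binding protein, rose from 5.56 ± 1.65 to 22.6 ± 3.49 CPM (2.02 ± 0.26, adjusted p = 0.0495). Of the 6 fits that left out 1 library, none called Igfbp2 (adjusted p 0.0542 to 0.237), and 1 each called Cxcl1 (0.0467 to 0.237), Cxcl2 (0.0492 to 0.237), Cxcl13 (0.0123 to 0.237) and Ereg (0.0319 to 0.108), with directions kept. Over all 13 alternative fits, 6 called Igfbp2, 6 Cxcl2, 6 Cxcl13, 8 Cxcl1 and 8 Ereg.

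In all, edgeR called 1 gene higher (Igfbp2) and 22 genes lower in KO among 14553 tested. Besides those above, the calls included Mmp3, the matrix protease stromelysin 1 (-2.16 ± 0.26, adjusted p = 0.0434). Kcnj8, a subunit of the ATP-sensitive potassium channel of vessel walls, fell by 2.09 ± 0.28 (adjusted p = 0.0495), and Gem, a small GTPase, by 1.81 ± 0.17 (adjusted p = 0.0287). Cyp3a25, a cytochrome P450, had 3 counts over the KO libraries and 143 over the WT libraries, a ratio of 42.5 (95% exact interval 14.3 to 209, adjusted p = 0.0483). Another 8 of the genes called lower were immunoglobulin variable segments. A further 4, named after their values were seen, were Ly6c1, the cytokine signalling inhibitor Socs3, the EGF receptor inhibitor Errfi1 and the glucocorticoid-induced Tsc22d3, with log2 fold changes of -1.68, -1.64, -1.13 and -1.02. Leaving out 1 library, 1 of 6 fits called each of Mmp3, Kcnj8, Gem, Ly6c1 and Socs3, and none called Cyp3a25 (adjusted p 0.0615 to 0.201), Errfi1 or Tsc22d3. In the upward direction the genes that came next without passing included Kcne3, Cdca7, Hao2, Cyp51, Dhcr7, Lilrb4a, Nxpe2 and Insig1. Their adjusted p lay between 0.0595 (Kcne3, log2 fold change 1.05 ± 0.17) and 0.0848 (Insig1, 1.05 ± 0.20). Lilrb4a had no count in any WT library and was at least 9.82-fold higher in KO. Lilrb4a lies on chromosome 10 and Cyp3a25 on chromosome 5. Derpc on chromosome 8 (0 CPM in KO, 2.26 in WT) and Krt90 on chromosome 15 (0.070 and 1.51) were also near absent in KO. Both were named after their values were seen, and neither passed in edgeR (adjusted p = 0.0848 and 0.0723). The neutrophil marker Ngp on chromosome 9 was near absent in KO too (0.0171 and 11.5 CPM). Whether a strain difference or read assignment contributed to these near-absent levels was not tested.

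The number of calls depended on the test. In edgeR 1895 genes had an unadjusted p below 0.05. DESeq2 called 106 genes higher and 431 lower, including all 23 edgeR calls, and limma-voom called 2 and 27, including 18 of the 23. In edgeR, median-ratio factors kept 9 of the 23 calls and the fit without KO 1 kept 12. The authors' deposited table lists 100 higher and 423 lower at the same threshold. In edgeR, leaving out KO 1 gave 0 higher and 29 lower, KO 2 0 and 1, KO 3 0 and 3, WT 1 1 and 5, WT 2 0 and 5, and WT 3 2 and 4, and Igfbp2 was not among the genes called higher in any of these fits.

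**Figure D1:**
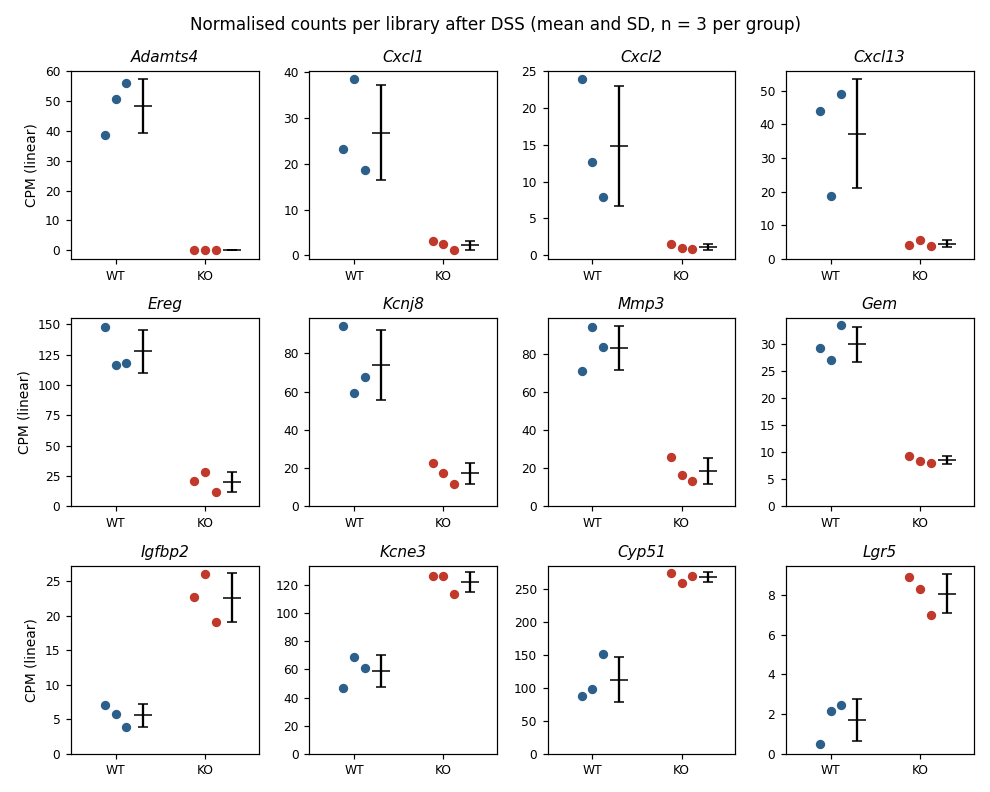
CPM of 12 genes in each of the 3 WT libraries (blue) and 3 KO libraries (red), on linear axes that start at or just below 0, with the group mean and SD in black. Adamts4 is at 0 in the 3 KO libraries, and in each panel the 3 KO points lie on one side of the 3 WT points; Kcne3, Cyp51 and Lgr5 did not pass over all genes tested.

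Inflammatory cytokine and chemokine genes fell as a group. All 17 tested members had log2 fold changes below 0 (median -1.99), and 16 of them fell when adjusted over the list alone, 2 over all genes tested (Cxcl1, Cxcl2) and 14 in DESeq2. Il11, a stromal cytokine of the IL-6 family, went from 33.4 ± 6.85 CPM in WT to 4.30 ± 2.39 in KO (-2.96 ± 0.44, adjusted p = 0.000837 over the list alone and 0.0595 over all genes), and Ptgs2, the inducible cyclooxygenase, from 33.5 ± 3.64 to 6.10 ± 4.04 (-2.47 ± 0.43, adjusted p = 0.00178 over the list alone). Camera with the preset correlation gave an adjusted p of 7.02e-29, against 0.146 with an estimated correlation. Without KO 3, DESeq2 called 10 members lower.

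Neutrophil markers were lower in KO to a similar degree. All 18 tested members lay below 0 (median -2.03), of which 15 fell when adjusted over the list alone, none over all genes tested in edgeR and 13 in DESeq2. Mmp8, the neutrophil collagenase, averaged 10.6 ± 5.77 CPM in WT and 0.586 ± 0.409 in KO (-4.16 ± 0.64, adjusted p = 0.00235 over the list alone), Ltf, the granule protein lactoferrin, 12.1 ± 5.24 and 1.99 ± 1.14 (-2.59 ± 0.46), and Fpr2, a formyl peptide receptor, 4.22 ± 0.862 and 0.913 ± 0.401 (-2.20 ± 0.40). Ngp, a granule protein, had 1 count over the KO libraries and 773 over the WT libraries. Camera's adjusted p was 8.60e-25, and 0.188 with an estimated correlation. The list's mean level lay lowest in KO 3, and without that library its median was -1.67 and DESeq2 called 8 members lower.

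The lists of epithelial host defence genes and of fetal-like regenerating epithelium genes, a program of wounded crypts, were lower in part. The libraries held RNA of epithelial, immune and stromal cells together. Which of these cells the falls came from was not tested, and neutrophil markers fell in the same libraries. Among 20 host defence genes 6 fell when adjusted over the list alone and none over all genes tested in edgeR (5 in DESeq2), among them the protease inhibitor Slpi (-1.76 ± 0.26), the acute-phase protein Saa3 (-3.05 ± 0.52), the siderophore binder Lcn2 (120 ± 76.8 to 15.1 ± 8.92 CPM) and the lectin Reg3g (-1.30 ± 0.39). Among 16 fetal-like genes 5 fell over the list alone, led by Ereg and by Plaur (36.4 ± 4.78 to 18.1 ± 3.59 CPM), Il1rn (-1.16 ± 0.31) and Il33 (-1.47 ± 0.46), 1 of them (Ereg) over all genes and 5 in DESeq2. Over the list alone, 3 host defence genes passed without KO 2 or WT 2, and fetal-like genes numbered 2 without KO 2, KO 3 or WT 3 and 3 without WT 1. Camera's adjusted p was 8.90e-06 and 8.16e-06 for these 2 lists, and 0.290 and 0.146 with an estimated correlation.

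Genes of the NF-kappaB feedback loop and immediate early genes, which respond to stress and to the handling of tissue, were lower in part. Of 16 NF-kappaB genes 5 fell over the list alone (4 in DESeq2), including the adhesion molecules Vcam1 (-1.34 ± 0.34) and Icam1 (-1.13 ± 0.32) and the inhibitor Nfkbia (-0.68 ± 0.17). Of 15 immediate early genes 7 fell over the list alone (4 in DESeq2), with Dusp1 at -1.35 ± 0.24, Egr1 at -1.46 ± 0.27 and Ier3 at -1.43 ± 0.29. None of either list passed over all genes tested in edgeR, and camera's adjusted p of 4.75e-06 for both became 0.304 and 0.310 with an estimated correlation, and fry gave 0.0964 and 0.113. Over the list alone, NF-kappaB genes numbered 0 without KO 2 or WT 2, 1 without WT 1 and 3 without KO 3, and immediate early genes 3 without KO 2 or WT 2 and 4 without WT 1.

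Intestinal stem cell genes and cholesterol synthesis genes rose. All 15 tested stem cell genes had log2 fold changes above 0 (median 0.70), and 9 rose when adjusted over the list alone, none over all genes tested in edgeR and 8 in DESeq2. Cdca7, a Myc target, went from 23.5 ± 5.66 CPM in WT to 54.8 ± 5.34 in KO (1.22 ± 0.21, adjusted p = 0.00446 over the list alone), the Wnt target Tnfrsf19 from 1.87 ± 0.134 to 4.69 ± 0.545 (1.33 ± 0.27), the crypt receptor Ephb3 from 15.7 ± 1.46 to 31.6 ± 7.63 (1.01 ± 0.21) and the Wnt receptor regulator Rnf43 from 14.0 ± 2.03 to 25.0 ± 1.21 (0.84 ± 0.17). Lgr5, the marker of crypt base stem cells, chosen after its values were seen, averaged 1.71 ± 1.05 and 8.06 ± 0.978 CPM (2.25 ± 0.50, adjusted p = 0.00493 over the list alone). All 20 cholesterol synthesis genes lay above 0 (median 0.93), with 18 rising over the list alone, none over all genes in edgeR and 14 in DESeq2. The sterol demethylase Cyp51 rose by 1.26 ± 0.22, the last enzyme of the pathway Dhcr7 by 0.77 ± 0.14 and the sterol sensor partner Insig1 by 1.05 ± 0.20 (each with adjusted p = 0.00248 over the list alone). Camera's adjusted p was 1.16e-11 for stem cell and 2.61e-25 for cholesterol genes, and 0.188 for both with an estimated correlation. Without KO 3 the medians were 0.74 and 0.97, and DESeq2 called 7 and 16 members higher.

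**Figure D2:**
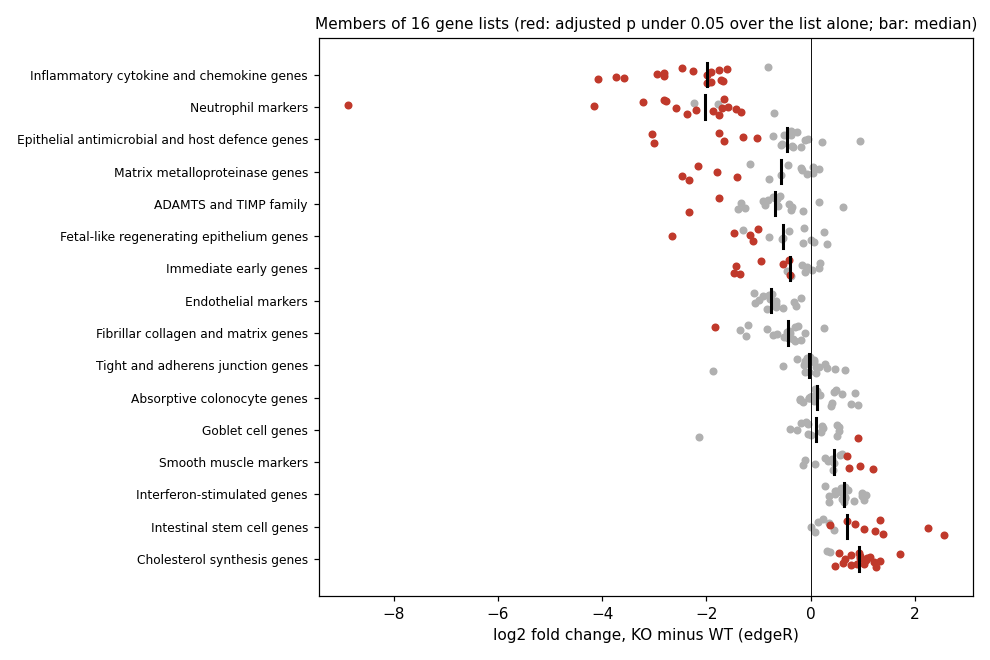
Log2 fold change (KO minus WT, edgeR) of each tested member of 16 gene lists, in red where the adjusted p over the list alone was below 0.05, with the list median as a black bar. The cytokine (median -1.99) and neutrophil (-2.03) lists lie to the left, and the stem cell (0.70) and cholesterol (0.93) lists to the right; the point near -9 is Ngp, with 1 count over the KO libraries.

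Some matrix protease genes were lower; Adamts4 itself is not a member of these lists. Among 15 matrix metalloproteinase genes 5 fell over the list alone, 1 over all genes tested (Mmp3) and 4 in DESeq2. The collagenase Mmp13 went from 86.7 ± 54.0 CPM in WT to 15.6 ± 5.83 in KO (-2.47 ± 0.46, adjusted p = 0.00470 over the list alone), stromelysin 2 (Mmp10) from 140 ± 77.7 to 27.7 ± 13.0 (-2.33 ± 0.47) and Mmp19 from 36.1 ± 13.1 to 10.3 ± 6.66 (-1.80 ± 0.51). Among 19 other ADAMTS and TIMP genes 2 fell over the list alone, Adamts1 (-2.34 ± 0.44) and the protease inhibitor Timp1 (-1.76 ± 0.43), none over all genes in edgeR and 3 in DESeq2, where Adamts15 (-1.25 ± 0.40) was the third. Over the list alone, metalloproteinase genes numbered 8 without KO 1 and 3 without KO 2 or WT 1, and ADAMTS and TIMP genes 8 without KO 1, 0 without KO 2 and 1 without KO 3, WT 1 or WT 3. Camera's adjusted p was 2.72e-07 and 8.21e-07, against 0.310 and 0.442 with an estimated correlation.

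Few genes of the matrix that these proteases act on passed. Among 17 proteoglycan, hyaluronan and reported substrate genes 1 fell over the list alone and in DESeq2, Cemip, a hyaluronan-degrading protein (81.6 ± 13.9 to 11.3 ± 6.98 CPM, -2.85 ± 0.46, adjusted p = 0.00435 over the list alone and 0.0644 over all genes), and the list was not called (camera adjusted p = 0.0654). Of the substrates themselves, Vcan averaged 42.8 ± 23.0 CPM in WT and 21.7 ± 14.4 in KO (-0.98 ± 0.60, adjusted p = 0.531, with -0.52 without KO 3 and -0.46 without WT 3) and Bcan stood at 0.87 ± 0.39 (adjusted p = 0.395). Acan had 1 count over all 6 libraries and was not detectable at this depth. Of 20 fibrillar collagen and matrix genes 1 fell over the list alone, the matricellular protein Thbs1 (348 ± 36.1 to 97.2 ± 36.7 CPM, -1.84 ± 0.29), and Tnc (-1.21 ± 0.33) joined it in DESeq2. That list's median of -0.43 was -0.02 without KO 3, and 2 of its genes passed over the list alone without KO 1 or KO 3. Without WT 1, 2 proteoglycan genes did, and that list was called without KO 1 or WT 1 and with the replicate block. Basement membrane genes gave no call over the list alone or in DESeq2, with Lama1 at -1.41 ± 0.56, but 9 of 18 fell over the list alone without KO 1. The collagen and basement membrane lists were called lower by camera (adjusted p = 4.11e-05 and 0.000139) and had 0.478 with an estimated correlation. Neither was called without KO 3, where the basement membrane median went from -0.54 to -0.27, and without KO 1 the medians were -1.09 and -1.02.

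Markers of other cell types moved as well. Plasma cell genes among 19 B lineage markers fell over the list alone, namely Mzb1 (-1.92 ± 0.39), Pou2af1 (-1.38 ± 0.34) and Jchain (737 ± 367 to 204 ± 95.5 CPM, -1.86 ± 0.46), none of them over all genes in edgeR and 3 in DESeq2. The list's median of -0.32 went to -1.47 without KO 3 and to 0.08 without KO 1, and its calls over the list alone to 11 without KO 3 and 0 without KO 2 or WT 2. The B cell surface gene Ms4a1, chosen after its values were seen, did not pass (0.07 ± 0.70, adjusted p = 0.975). Of 119 tested immunoglobulin variable segments, which share reads with near-identical copies, 113 had log2 fold changes below 0 (median -2.66), and edgeR called 8 and DESeq2 60 lower. Of 19 T and NK cell markers 2 fell over the list alone, Gzma (-2.12 ± 0.31) and Ctla4 (-1.24 ± 0.31), none over all genes in edgeR and 1 in DESeq2, and 1 passed without KO 1, KO 2, WT 1, WT 2 or WT 3. Blood and erythroid genes fell in all 6 members over the list alone (median -2.31), including Alas2 (-2.52 ± 0.63) and the haemoglobin genes Hba-a2 (-2.35 ± 0.66) and Hbb-bt (-2.28 ± 0.66), which are near-identical to their neighbours, with none over all genes in edgeR, 2 in DESeq2 and none over the list without KO 2. The blood median was -1.21 without WT 3, whose mean level for the list was 2.48 against 0.24 in WT 1 and 0.49 in WT 2. Camera called these 3 lists lower (adjusted p = 0.000565, 0.000495 and 5.84e-07), with 0.477, 0.478 and 0.310 under an estimated correlation, and called neither the B lineage nor the T and NK list without KO 1.

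Smooth muscle markers were the only cell type list besides stem cells called higher by camera (median 0.44, adjusted p = 0.000135, and 0.475 with an estimated correlation). Of 14 members 4 rose over the list alone, none over all genes in edgeR and 3 in DESeq2, with Actg2 going from 259 ± 71.1 to 590 ± 104 CPM (1.19 ± 0.25) and Des, the muscle intermediate filament, from 273 ± 66.0 to 526 ± 78.5 (0.95 ± 0.24). No member passed over the list alone without KO 2, KO 3, WT 2 or WT 3. Camera called 5 further cell type lists lower, none with a member past the threshold over the list alone. Monocyte and macrophage markers had a median of -0.62 (adjusted p = 9.60e-06), fibroblast markers -0.51 (0.000112), endothelial markers -0.77 (5.84e-07), enteric neuron and glia markers -0.38 (0.00155) and adipocyte markers -1.05 (0.0289). With an estimated correlation their adjusted p lay between 0.475 and 0.533. The adipocyte list was not called with limma-voom (median -0.05) or without KO 1, KO 2, WT 2 or WT 3 (-0.28 without WT 3), nor the neuron and glia list without KO 1 or WT 1, and the macrophage median was -1.13 without KO 1 and -0.41 without KO 3, the fibroblast one -0.90 and -0.34, and the endothelial one -0.44 without KO 3. Among their leading members, Itgam stood at -1.25 ± 0.41, Pdpn at -1.26 ± 0.34, Pecam1 at -0.99 ± 0.29, Tubb3 at -0.72 ± 0.22 and Plin4 at -1.30 ± 0.37, none past the threshold in edgeR, while DESeq2 called all of these but Tubb3 and in all 1 macrophage, 1 fibroblast, 2 endothelial, 0 neuron and glia and 2 adipocyte markers lower. Over the list alone, 7 macrophage, 8 fibroblast and 8 endothelial markers fell without KO 1, 1 endothelial and 1 neuron marker without KO 3, and 6 adipocyte markers without WT 1.

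**Figure D3:**
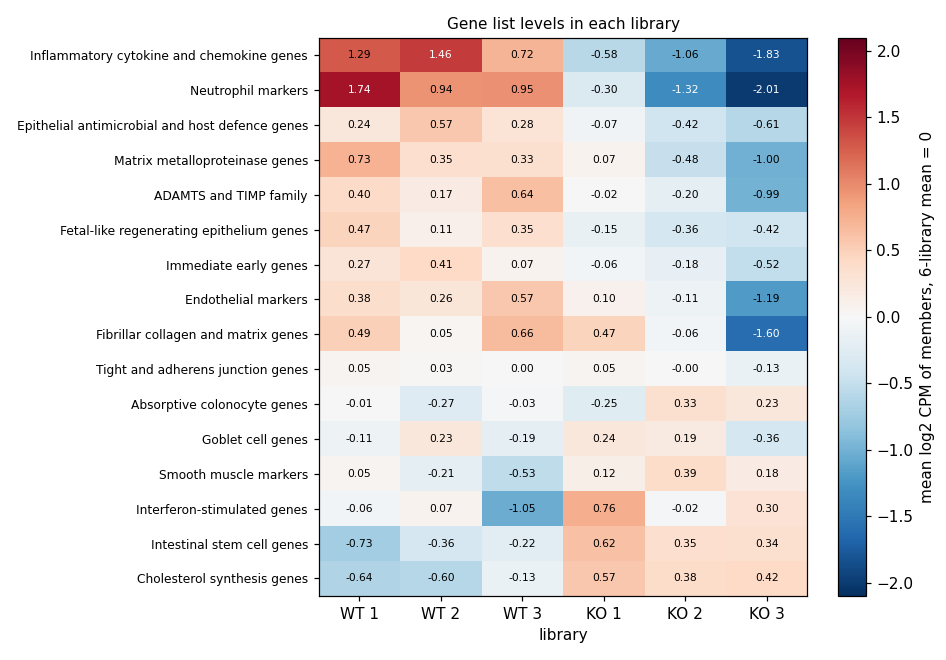
Mean log2 CPM of the members of 16 gene lists in each library, relative to the mean of the 6 libraries. Fibrillar collagen and endothelial genes are lowest in KO 3 (-1.60 and -1.19). The endothelial, cytokine, stem cell and cholesterol lists are among those that separate the 3 KO from the 3 WT libraries.

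Lists of differentiated epithelium gave few calls. Goblet cell, absorptive colonocyte, enteroendocrine, small intestine, squamous and junction lists were not called by camera, with medians of 0.11, 0.12, 0.21, 0.18, -0.31 and -0.03. When 1 library was left out these medians changed sign, running from -0.08 to 0.25, -0.03 to 0.15, -0.12 to 0.30, -0.31 to 0.35, -0.54 to 0.21 and -0.07 to 0.03, and the goblet list was called higher without KO 3 and with DESeq2. Agr2, a disulfide isomerase of mucus secretion, was the goblet gene that rose over the list alone and in DESeq2 (1025 ± 84.0 to 1932 ± 167 CPM, 0.91 ± 0.17, adjusted p = 0.0109 over the list alone and 0.0849 over all genes). The water channel Aqp8 stood at 0.91 ± 0.35, the peptide hormone gene Insl5 at 1.19 ± 0.52 and the small intestinal lectin Itln1 at -3.70 ± 1.01, none past the threshold over its list, although DESeq2 called Itln1. Itln1 lies within 10 Mb of Adamts4. Sbsn, 1 of 4 tested squamous genes, fell over the list alone (-2.11 ± 0.63), and the tight junction gene Cldn1 was called lower in DESeq2 (-1.87 ± 0.47). Over the list alone Sbsn did not pass without KO 1, KO 2, KO 3 or WT 3. In the other lists 2 goblet genes passed without KO 3 and none without WT 1 or WT 2, 2 small intestine genes without KO 1, 2 absorptive genes without WT 3 and 1 junction gene without WT 2.

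Among interferon, metabolic and growth lists, single genes rarely passed. All 20 interferon-stimulated genes lay above 0 (median 0.63, camera adjusted p = 1.03e-07, and 0.475 with an estimated correlation), but none passed over the list alone and only Ifit1 (1.02 ± 0.31) in DESeq2. Over the list alone 1 passed without WT 1, and up to 7 did among the 13 alternative fits. The median was 0.33 without WT 3, the lowest library for this list at -1.05, and 0.36 without KO 1. Of 23 interferon-gamma and MHC class II genes 14 lay below 0 (median -0.65, camera adjusted p = 0.000586, and 0.533 with an estimated correlation), and 4 fell over the list alone, the antigen-loading genes H2-DMb1 (-1.30 ± 0.32) and H2-DMa (-1.08 ± 0.27), the tryptophan-degrading enzyme Ido1 (-1.71 ± 0.46) and H2-Eb1 (-0.95 ± 0.27), with 6 in DESeq2. None passed when any library but WT 1 was left out, and 12 without WT 1, and the list was not called without WT 2, where the median was -0.37. Cell cycle, oxidative phosphorylation and mitochondrially encoded genes were called higher by camera (medians 0.58, 0.28 and 0.71, adjusted p = 6.12e-07, 0.000873 and 0.000207), with 0.475, 0.533 and 0.478 under an estimated correlation and no member past the threshold over its list or in DESeq2, but all 13 mitochondrially encoded genes passed over the list alone without KO 1. Without KO 3 the medians of these 3 lists were 0.42, 0.11 and 0.44 and oxidative phosphorylation was not called, and the cell cycle median was 0.27 without WT 1, where the list was lowest at -1.12. Pcna stood at 0.49 ± 0.16, Cycs at 0.54 ± 0.20 and mt-Atp6 at 0.85 ± 0.30. The inflammasome, fatty acid oxidation and unfolded protein response lists were not called (medians 0.15, 0.09 and 0.14), apart from the unfolded protein response without KO 3, where its median was 0.27 (-0.01 without KO 1). In them the inflammasome sensor Nlrp3 (-1.60 ± 0.28) and the lipase inhibitor Angptl4 (-2.26 ± 0.36) fell over their lists and the gasdermin Gsdmc2 rose (0.69 ± 0.17), while Manf stood at 0.48 ± 0.19. Inflammasome genes rising over the list alone numbered 2 without KO 1 or WT 3 and 0 without KO 2, KO 3, WT 1 or WT 2.

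Taking all lists, camera with the preset correlation called 26 of 36, 7 higher and 19 lower in KO. None was called with an estimated correlation, where 6 lists had an unadjusted p below 0.05, and fry called 4: the cytokine, fetal-like, stem cell and cholesterol lists, each with an adjusted p of 0.0495.

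Pathways of the deposited KEGG annotation were tested with camera, which called 131 of 326 pathways, 88 lower and 43 higher. With an estimated correlation it called none, 28 having an unadjusted p below 0.05. Complement and coagulation cascades led those lower in KO (55 genes, median -0.79, adjusted p = 5.65e-17), followed by cytokine-cytokine receptor interaction (187 genes, median -0.49, adjusted p = 5.10e-16). Steroid biosynthesis led those higher (18 genes, median 0.65, adjusted p = 3.91e-08), with 9 of its genes called higher in DESeq2, followed by oxidative phosphorylation (122 genes, median 0.31, adjusted p = 2.70e-07) and DNA replication (35 genes, median 0.47, adjusted p = 4.38e-07). With an estimated correlation the adjusted p of these 5 lay between 0.463 and 0.628, and without KO 3 the preset correlation called 79.

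Genes around Adamts4 were tested as a group because a targeted allele can carry flanking sequence of another strain. Within 10 Mb on chromosome 1, edgeR called 1 of 163 tested genes, Adamts4 itself, against 22 of 14369 elsewhere (two-sided Fisher's exact p = 0.229). With Adamts4 left out, a choice made after the result was seen, edgeR called 0 of 162, of which 32 had an unadjusted p below 0.05. Over all tested genes 1895 of 14553 had an unadjusted p below 0.05 in edgeR, a smaller share. DESeq2 then called 10 of 178, against 526 of 15437 elsewhere (odds ratio 1.69, Fisher's exact p = 0.140), and 8 of 103 within 5 Mb (odds ratio 2.39, Fisher's exact p = 0.0253). The genes DESeq2 called within 10 Mb included, named after their values were seen, the endothelial selectin Selp (-2.24 ± 0.47), the venular chemokine receptor Ackr1 (-1.45 ± 0.26) and Rgs4 (-1.05 ± 0.18). They also included Itln1 (-3.70 ± 1.01, DESeq2 adjusted p = 0.0377), which lies close to Adamts4 at 171518122 to 171535294.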

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

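The likelihood-ratio test of edgeR, DESeq2 without KO 3, fry, the estimated correlation for pathways, the count near Adamts4 with Adamts4 left out and the list medians and member counts under each setting were chosen only after the results were seen. The number of genes higher in KO, 1 in edgeR, was 0 with RLE factors, 2 with limma-voom, 3 without a count filter, 3 with a replicate block, 2 with limma-trend on TPM and 20 at an adjusted p below 0.1. It was 106 with DESeq2, 112 with DESeq2 without KO 3 and 80 with the likelihood-ratio test, and between 0 (without KO 1) and 2 (without WT 3) when 1 library was left out. The number lower, 22 in edgeR, was 9 with RLE and 38 with upper-quartile factors, 66 without a count filter, 78 with the block, 66 with limma-trend on TPM and 114 at an adjusted p below 0.1. It was 431 with DESeq2, 372 with DESeq2 without KO 3 and 382 with the likelihood-ratio test, and between 1 (without KO 2) and 29 (without KO 1) when 1 library was left out. The likelihood-ratio test used the same counts, filter and TMM factors as the main test. The choice of test within edgeR was therefore enough to move the counts from 1 and 22 to 80 and 382. What caused the other differences was not tested.

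The 26 gene lists called became 0 with an estimated correlation and 4 with fry. The 131 pathways called became 0 with an estimated correlation, and 79 without KO 3 to 146 without KO 2. The 1 called gene near Adamts4 became 11 with DESeq2, 2 with the block and 0 with Adamts4 left out. The block assumes that equal replicate numbers pair libraries. The deviations of same-numbered KO and WT libraries correlated at -0.42, -0.15 and -0.43, which gives no sign of pairing. Deviations from a mean of so few libraries constrain each other, so these values cannot exclude pairing.

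Among gene-level values Adamts4 was called in every fit. The B and plasma cell median changed sign without KO 1, to 0.0850, and was -1.47 without KO 3. Col1a1 went from -0.93 without KO 1 to 0.27 without KO 3. Ms4a1 was -0.29 with limma-voom and -0.26 with the block, and went from 0.56 without KO 1 to -0.86 without KO 3.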

Other observations

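The counts of genes, lists and pathways called were planned, while the regrouping of libraries, the calls over the list alone summed over all lists, the shares of list medians kept without KO 3 and the tests of immunoglobulin genes, Nnt, epithelial share and the region near Adamts4 with that gene left out were chosen only after the results were seen. Immunoglobulin constant genes were lower along with the variable segments. Their CPM, summed over 12 tested genes, averaged 1782 ± 889 in KO and 6888 ± 3852 in WT, against 428 ± 282 and 2087 ± 1326 for the variable segments (exact two-sided permutation p = 0.1 for each, the smallest that 3 against 3 allows). Nnt, the mitochondrial transhydrogenase that differs between substrains of C57BL/6, was split over 2 overlapping gene models on chromosome 13. One model (ENSMUSG00000025453) averaged 6.30 ± 2.18 CPM in KO and 20.1 ± 7.09 in WT, while the other (ENSMUSG00000116207) had 197 to 230 counts in the KO libraries and 0 to 27 in the WT libraries (edgeR adjusted p = 0.101 and 0.106, DESeq2 0.000118 and 0.216).

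The immunoglobulin fall may come from reads moving between near-identical segments, from a few expanded clones in the WT colons, or from fewer plasma cells in the KO colons. Moving reads would leave the sum unchanged, but the summed variable segments had a log2 ratio of -2.29, which argues against it. Expanded clones might leave most segments level, and 113 of 119 lay below 0. That count cannot decide, because segments high in WT alone pass the expression filter and near-identical segments share reads. Fewer plasma cells would lower constant genes as much, and the summed log2 ratios differed by only -0.33. That goes with fewer plasma cells and with less transcription per plasma cell. It does not exclude expanded clones in WT, which would carry constant genes too.

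The neutrophil, cytokine, stem cell and cholesterol differences could reflect KO 3 alone, or a larger share of epithelium in the KO tissue pieces. Without KO 3 each list kept at least 82.2% of its median, which argues against the first, while the fibrillar collagen list kept 4.99%, so that difference depended on KO 3. If a larger epithelial share had raised the stem cell genes, it would have raised other epithelial genes by about as much. The 55 junction, goblet and absorptive genes had a median of 0.0599 (95% interval over the genes -0.04 to 0.20), against 0.70 for stem cell genes. When each library was left out in turn, the junction, goblet and absorptive medians reached at most 0.03, 0.25 and 0.15. The stem cell median stayed at 0.59 or above. These values argue against a larger share of epithelium as a whole for the stem cell and cholesterol lists. They do not test a larger share of stem cells within the epithelium. Nor do they show that the epithelial share was equal in both groups, or whether it contributed to the lower neutrophil and cytokine lists. Neutrophil number and neutrophil gene activity were not told apart by these data.

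The Nnt difference may come from reads being assigned to one or the other model, or from a strain difference between the genotypes. The 2 models share 15 of 17 exons, and their summed CPM had a log2 ratio of -0.16 (exact permutation p = 0.9), which is consistent with a change of assignment, and sequence or splice differences between strains could produce it. Flanking donor chromosome around Adamts4 might add called genes there, and the odds ratio of 1.69 within 10 Mb in DESeq2, with Adamts4 left out, leaves this open (Fisher's exact p = 0.140, and odds ratio 2.39 with p = 0.0253 within 5 Mb).

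The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. For the first 5 results here the real division alone, 1 of 10, gave so many. It had 23 edgeR calls against at most 1 in any other, 537 DESeq2 calls against 99, 26 lists called by camera with the preset correlation against 23, 131 pathways against 83, and 114 calls over the list alone, summed over all lists, against 27. With Adamts4 left out, edgeR called 0 genes near it in all 10 divisions. In the real division 32 of 162 genes there had an unadjusted p below 0.05, against 1895 of 14553 over all tested genes. DESeq2 called 10 there in the real division.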
